A study of Rattus norvegicus with 12 samples.

How the data were processed

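Small RNA libraries were made from the livers of Fischer-344 rats, an inbred strain, after a sham operation or partial hepatectomy, the surgical removal of part of the liver after which the remnant regrows. Per the labels' protocols, total RNA was extracted with TRIzol, libraries were prepared with the Illumina TruSeq small RNA kit, purified on a gel, and sequenced on an Illumina HiSeq instrument. The labels gave 6 libraries of normal, sham-operated liver (pre_PH, replicates 1 to 6) and 2 libraries each at 24, 48 and 168 hours after hepatectomy. The labels did not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical. No sequencing batch or date was in the labels, so a shared preparation of the 2 libraries of a time cannot be told apart from that time.

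The authors' deposited tables listed, for each library, the names of piRNAs (PIWI-interacting RNAs, small RNAs that guide PIWI proteins and are best known from the germ line) with their read count, whole numbers with no normalization per the file headers. A second column of deposited counts gave the number of distinct read sequences behind each read count. Another 2 columns gave the authors' percent of each piRNA, per the file headers relative to all reads of the library and to the reads mapped to piRNAs. Per the submitters' processing notes, CASAVA 1.8, cutadapt, DESeq 1.14.0 and the genome build rn4 were used, with no role stated for any of them. The aligner, the mismatches allowed, the length filter and the treatment of reads that match several piRNAs are not given in the sources used here. Names with near-identical sequences can therefore share or split reads, and every value of a single piRNA carries that uncertainty. Genome positions, sequences and microRNAs were not used here, so positional and sequence groups and cell type markers that had been listed were not analysed. A piRNA not listed in a library was taken as a count of 0 there.

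The authors' library total was obtained from the ratio of the read count to the percent of all reads, which gave 1 constant per library, from 20741811 to 31467460 reads. That this constant is the number of reads of the library was read from the column's name. The listed piRNA reads numbered 120844 to 351818 per library, between 99.2% and 99.9% of the total mapped to piRNAs that the authors' other percent implies, and the remainder was not analysed here. At these depths 3 reads, the limit that a count of 0 allows, correspond to between 0.0953 and 0.145 RPM of library reads. Intervals and such limits cover counting error only, since reads copied by PCR without molecular identifiers are not independent molecules. Chi-square tests of all replicate pairs found no pair that agreed within sampling noise.

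The choices that follow were fixed before the data were examined, apart from the additions named at the end. Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit with robust estimation and F-test), TMM scaling and the filterByExpr filter, which left 80 piRNAs in the fit of 4 groups and 52 in the pooled comparison of 6 against 6 libraries. All 12 libraries and all 4 groups entered 1 fit, since each time had only 2 libraries. A piRNA was called at a Benjamini-Hochberg adjusted p under 0.05. TMM factors ranged from 0.479 to 1.51, and the biological coefficient of variation was 0.591. Normalised CPM values are counts divided by the TMM-scaled total of listed piRNA reads, so they are relative to the other piRNAs and not to the whole library. The standard error of a log2 fold change was taken as its size divided by the square root of F. Where a group had 1 to 3 reads in all, a ratio of pooled rates is given with an exact conditional 95% interval. The rate is the summed reads of a group over its summed TMM-scaled totals. Where a group had 0 reads, a bound against 3 reads over the group is given.

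The number of piRNAs detected was compared after thinning each library at random to 120844 piRNA reads, as the mean of 100 draws. Per-library measures were compared by exact two-sided permutation tests, with 28 splits of 2 against 6 libraries (smallest possible p 0.0357) and 924 splits of 6 against 6, and adjusted over the 4 comparisons of a measure. Shares of reads carry Wilson 95% intervals where a single library is given. Groups of piRNAs were tested with camera from limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. The groups, the piRNAs found in all 12 libraries and the 20 most abundant, were defined on these same samples and are not independent evidence of a direction. Correlations of fold changes between times were set beside 100 simulations of unchanged groups against the shared pre_PH libraries.

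The piRNAs named were set by rule. At each time, these were the 10 largest rises and 10 largest falls past the threshold whose values in both libraries lay outside the range of the 6 pre_PH libraries, with the 5 smallest p-values added where fewer than 5 passed. Between times, and in the pooled comparison, the 5 largest rises and falls past the threshold were named, between times only those whose libraries did not overlap. The 10 most abundant piRNAs were named whatever their test. Alternatives were DESeq2 1.42.0, limma-voom, other scalings, other filters and thresholds, a block for the replicate number, a fit of only the compared groups, and leaving out each library. Simulated counts with known changes held as many rises as falls and the same spread for every piRNA. The real data need not, so the rates that follow may not hold for the real comparisons. On these counts, the 48h comparison recovered 35.8% of 4-fold and 93.2% of 16-fold changes and called 0.576% of unchanged piRNAs, with a median of 75.5 piRNAs tested over 20 runs. The 24h comparison recovered 32.9% and 92.3% of these, the 168h comparison 38.4% and 91.0%, and the pooled comparison 80.5% of 4-fold changes. Per-library values used Python 3.11.15, pandas 2.3.3 and scipy 1.17.1. Scaling to the authors' library total, alone and without each 48h library, and thinning to one library total were added after the data had been seen.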

Results

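Small RNA sequencing of rat liver was used to ask which piRNAs change in amount after partial hepatectomy. The series held 12 libraries, with 6 from sham-operated liver (pre_PH) and 2 each at 24, 48 and 168 hours after surgery. Library totals ranged from 20741811 reads in 48h replicate 1 to 31467460 in 48h replicate 2, and listed piRNA reads from 120844 in 48h replicate 1 to 351818 in pre_PH replicate 3. The piRNAs listed numbered 701 over all libraries, of which 61 were found in all 12 and 335 in 1 library only.

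Reads of piRNAs were a small part of each library in all groups. They made up 0.713% ± 0.296 (SD, n = 6) of library reads in pre_PH, 0.611% ± 0.271 (SD, n = 2) at 24h, 0.691% ± 0.154 (SD, n = 2) at 48h and 0.471% ± 0.0899 (SD, n = 2) at 168h. Among single libraries the share ran from 0.408% in 168h replicate 1 (95% Wilson interval 0.405 to 0.410%) to 1.25% in pre_PH replicate 3 (1.249 to 1.257%). One library at 24h and 1 at 168h lay below the pre_PH range. The geometric mean at 168h, which a test on log2 share compares, was 0.695 of that in pre_PH. No time passed (exact permutation tests on log2 share, adjusted p = 0.905 at 24h, 0.929 at 48h and 0.835 at 168h), but with 28 splits a single time could not have done so after correction, and a difference is not excluded. The 6 libraries after hepatectomy pooled did not pass either (0.591% ± 0.176, exact permutation adjusted p = 0.835).

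More piRNA species were detected at 48h than in any other group. At an equal 120844 piRNA reads, 328 and 329 piRNAs were detected in the 48h libraries, against 143 ± 31.9 (SD, n = 6, range 110 to 192) in pre_PH, a ratio of 2.30. The numbers at 24h (123 ± 11.9, n = 2) and 168h (159 ± 13.5, n = 2) lay within the pre_PH range. Both 48h libraries lay above all 6 pre_PH libraries, which gave the smallest p possible with 28 splits (exact permutation p = 0.0357, adjusted p = 0.143), so the difference did not pass the correction and could not have done so in this design unless other times had differed as well. Among piRNAs with at least 10 reads, 93 ± 15.6 (n = 2) were found at 48h and 51 ± 5.29 (n = 6) in pre_PH. A total of 227 names were seen at 48h and in no other group, 137 of them with 1 read in all. None of these 227 had more than 8 reads in a library, and together they made up 0.118% and 0.0966% of the piRNA reads of the 48h libraries.

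**Figure D1:**
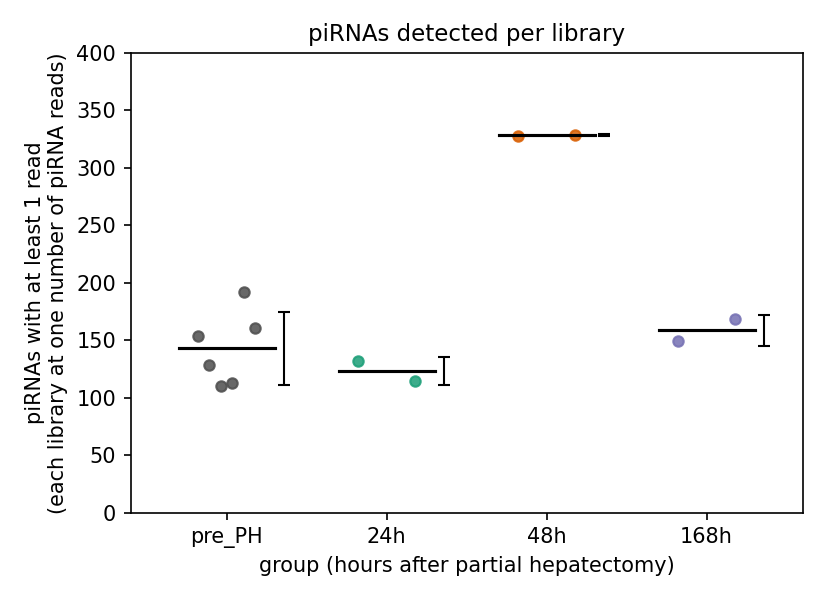
Number of piRNAs with at least 1 read (vertical axis) in each library after thinning to 120844 piRNA reads, by group (horizontal axis). Points are libraries, horizontal lines group means and bars 1 SD; the 48h libraries sit at 328 and 329, above the pre_PH range of 110 to 192.

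A few species made up most piRNA reads in all groups. The 10 most abundant piRNAs held 92.0% ± 2.14 (SD, n = 6) of piRNA reads in pre_PH, 93.9% ± 1.65 at 24h, 90.1% ± 1.42 at 48h and 88.1% ± 3.19 at 168h (n = 2 each), and no time passed the test (exact permutation adjusted p = 0.418 for each). The 3 most abundant, rno_piR_000685, rno_piR_005556 and rno_piR_004288, held 67.0% ± 5.41 in pre_PH, 65.8% ± 1.90 at 24h, 40.8% ± 3.21 at 48h and 45.5% ± 26.5 at 168h. At 48h both libraries lay below the pre_PH range (exact permutation p = 0.0357, adjusted p = 0.121), which did not pass either. The most abundant, rno_piR_000685, held 44.0% ± 5.79 in pre_PH, 34.9% ± 2.56 at 24h, 24.1% ± 1.16 at 48h and 30.7% ± 18.4 at 168h. Its share was below the pre_PH range in both libraries at 24h and at 48h (exact permutation p = 0.107 and 0.0357, adjusted p = 0.143 and 0.0714), while the pooled comparison gave p = 0.0130 (adjusted p = 0.0519). Its normalised count at 48h was lower by a log2 fold change of -1.69 ± 0.85 (SE), which did not pass (edgeR adjusted p = 0.112) but did with DESeq2 (adjusted p = 0.0189, over all alternatives 0.0127 to 0.633) and without 24h replicate 2 or 168h replicate 1. The share of rno_piR_004288 was 13.9% ± 8.84 in pre_PH and 3.61% ± 1.19 at 48h, and that of rno_piR_005567 was 2.80% ± 1.89 and 13.9% ± 4.55, a rise in normalised count by a log2 fold change of 1.82 ± 0.70 (SE, edgeR adjusted p = 0.0381). That rise was lost when any 1 of 8 libraries was left out (pre_PH replicates 3, 4 and 6, both 24h and both 48h libraries, and 168h replicate 1). At 168h rno_piR_005567 held 41.5% of reads in replicate 2 (95% Wilson interval 41.3 to 41.8%) and 3.80% in replicate 1. The shares of rno_piR_005556 were 8.98% ± 6.99 in pre_PH and 23.0% ± 4.83 at 24h, and its count did not pass the test at any time. The other 6, rno_piR_005901, rno_piR_005900, rno_piR_005787, rno_piR_008639, rno_piR_000030 and rno_piR_005359, passed it at no time either, apart from a lower value of rno_piR_005359 at 48h when 48h replicate 1 or 168h replicate 1 was left out.

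**Figure D2:**
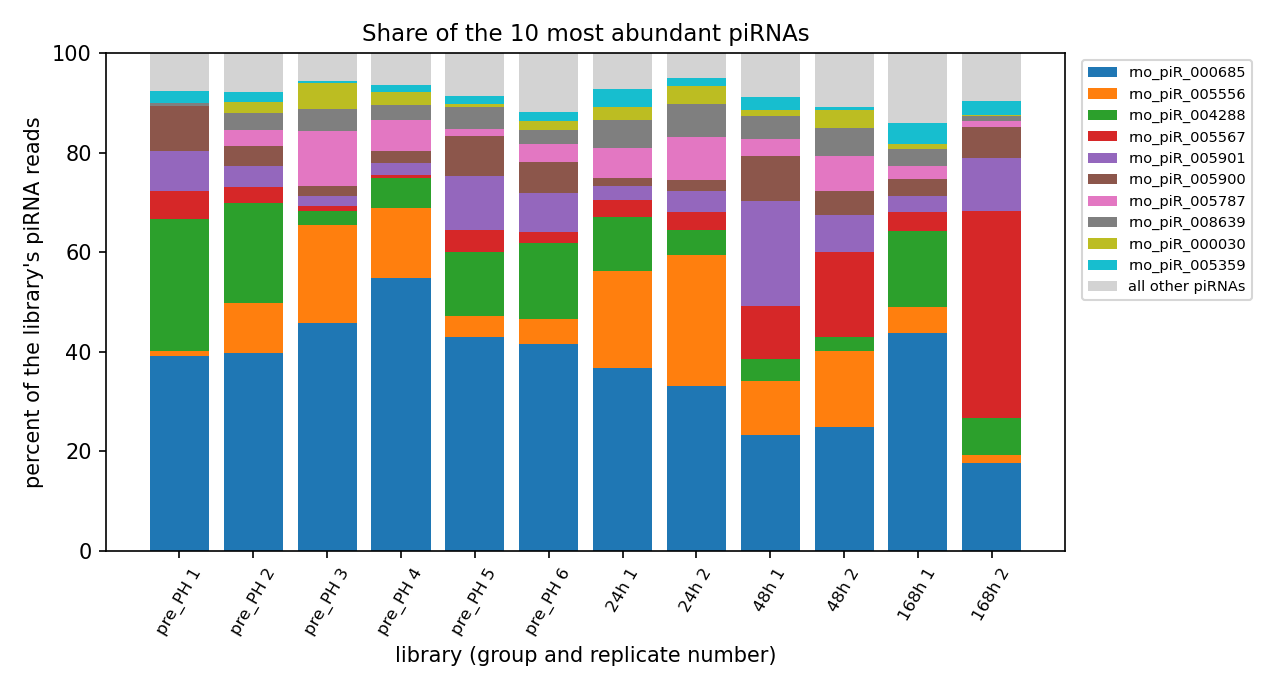
Percent of each library's piRNA reads (vertical axis) held by each of the 10 most abundant piRNAs, with all others in grey, for the 12 libraries (horizontal axis). The share of rno_piR_000685 is 23.3 and 24.9% in the 48h libraries against 39.3 to 54.8% in pre_PH, and rno_piR_005567 takes 41.5% of 168h replicate 2.

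Early in regeneration, at 24h, few single piRNAs were called against pre_PH. That comparison recovered only 32.9% of simulated 4-fold changes, so few calls do not show that little differed. One piRNA, rno_piR_020049, was higher by a log2 fold change of 3.68 ± 0.76 (SE), with 580 ± 389 normalised CPM (SD, n = 2) against 44.4 ± 23.1 (n = 6, edgeR adjusted p = 0.00649). Another, rno_piR_001415, was lower by a log2 fold change of -2.43 ± 0.64, at 147 ± 36.9 against 795 ± 210 (edgeR adjusted p = 0.0366). These were the only 2 calls among 80 piRNAs tested with edgeR, 9 having an unadjusted p under 0.05. The next 3 by p, rno_piR_015359, rno_piR_000219 and rno_piR_005633, had log2 fold changes of -1.84, -1.82 and -1.77 and did not pass (edgeR adjusted p = 0.235, 0.262 and 0.262). The rise of rno_piR_020049 was lost without 24h replicate 1 and with limma-voom, and the fall of rno_piR_001415 when any 1 of 6 libraries was left out (pre_PH replicates 2, 3 and 6, both 24h libraries and 168h replicate 2). Scaling to the piRNA total, upper-quartile scaling and TMM without the 10 most abundant piRNAs left the 1 rise and no fall. Scaling to the authors' library total gave 1 rise and 4 falls.

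At 48h, the time with the most calls, 27 of 80 piRNAs tested were higher and 10 lower than in pre_PH. The best-supported change was in rno_piR_031043, at 17710 ± 2625 normalised CPM (SD, n = 2) against 1177 ± 244 (n = 6), a log2 fold change of 3.91 ± 0.47 (SE, edgeR adjusted p = 1.6e-06). Several piRNAs that were nearly unseen in sham-operated liver reached low counts. For rno_piR_035899, 1 read in all was found in the 6 pre_PH libraries and 16 and 31 at 48h (edgeR adjusted p = 7.9e-05), a ratio of 85.0 with a 95% counting interval of 14.5 to 3430. The log2 fold changes of rno_piR_009544, rno_piR_011266 and rno_piR_033815 were 4.76 ± 0.91, 4.59 ± 0.86 and 4.20 ± 0.84 (edgeR adjusted p = 0.00035, 0.00032 and 0.00050). Further rises were seen in rno_piR_034827 (log2 fold change 3.95), rno_piR_037601 (3.94), rno_piR_024382 (3.90), rno_piR_004937 (3.44) and rno_piR_003606 (3.44), with edgeR adjusted p between 7.9e-05 and 0.0025. The 27 piRNAs that rose held 14.2% and 20.5% of the piRNA reads of the 48h libraries, against 0.834 to 5.73% in pre_PH. Most of that was rno_piR_005567 alone, with 10.7% and 17.1% at 48h against 0.691 to 5.54%, whose call did not hold with single libraries left out. Without it the other 26 held 3.53% and 3.35% against 0.0787 to 0.310%, of which rno_piR_031043 made up 2.38% and 2.80%.

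The piRNAs that fell at 48h included abundant ones. The level of rno_piR_004288 was 24460 ± 7215 normalised CPM at 48h and 134600 ± 63360 in pre_PH, a log2 fold change of -2.46 ± 0.85 (SE, edgeR adjusted p = 0.0225). That of rno_piR_000746 was 1336 ± 761 against 10480 ± 4814 (log2 fold change -2.97 ± 0.75, edgeR adjusted p = 0.0029). The log2 fold change of rno_piR_000753 was -3.07 ± 0.72 (edgeR adjusted p = 0.0015). Smaller falls were found in rno_piR_000575 (log2 fold change -2.60), rno_piR_001825 (-2.40), rno_piR_000562 (-2.06), rno_piR_000324 (-2.02), rno_piR_032799 (-1.91) and rno_piR_002302 (-1.65), with edgeR adjusted p from 0.0066 to 0.0326.

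The balance of rises and falls at 48h depended on scaling and on a single library. Against 27 rises and 10 falls with TMM, scaling to the piRNA total gave 31 and 2, and upper-quartile scaling 33 and 5. Without 48h replicate 1 the calls were 4 rises and 15 falls, which became 32 and 2 when that same set of libraries was scaled to the authors' library totals. The rises of rno_piR_031043, rno_piR_035899, rno_piR_009544 and rno_piR_011266 passed in each of these fits, whereas the other 6 named rises were lost without 48h replicate 1, that of rno_piR_003606 also without 48h replicate 2. Of the named falls, that of rno_piR_000753 passed in all settings and with any library left out. That of rno_piR_000746 passed in all but the fit to the authors' totals without 48h replicate 1. The other 7 falls were lost with scaling to the piRNA total. Those of rno_piR_004288 and rno_piR_000575 were also lost without 48h replicate 2, and that of rno_piR_002302 without pre_PH replicate 1 or 168h replicate 2. The falls of rno_piR_004288, rno_piR_000575, rno_piR_032799 and rno_piR_002302 were lost with upper-quartile scaling and with the stricter filters too. The replicate block, which left only pre_PH replicates 1 and 2 to compare with, removed those of rno_piR_000575, rno_piR_000324, rno_piR_032799 and rno_piR_002302.

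**Figure D3:**
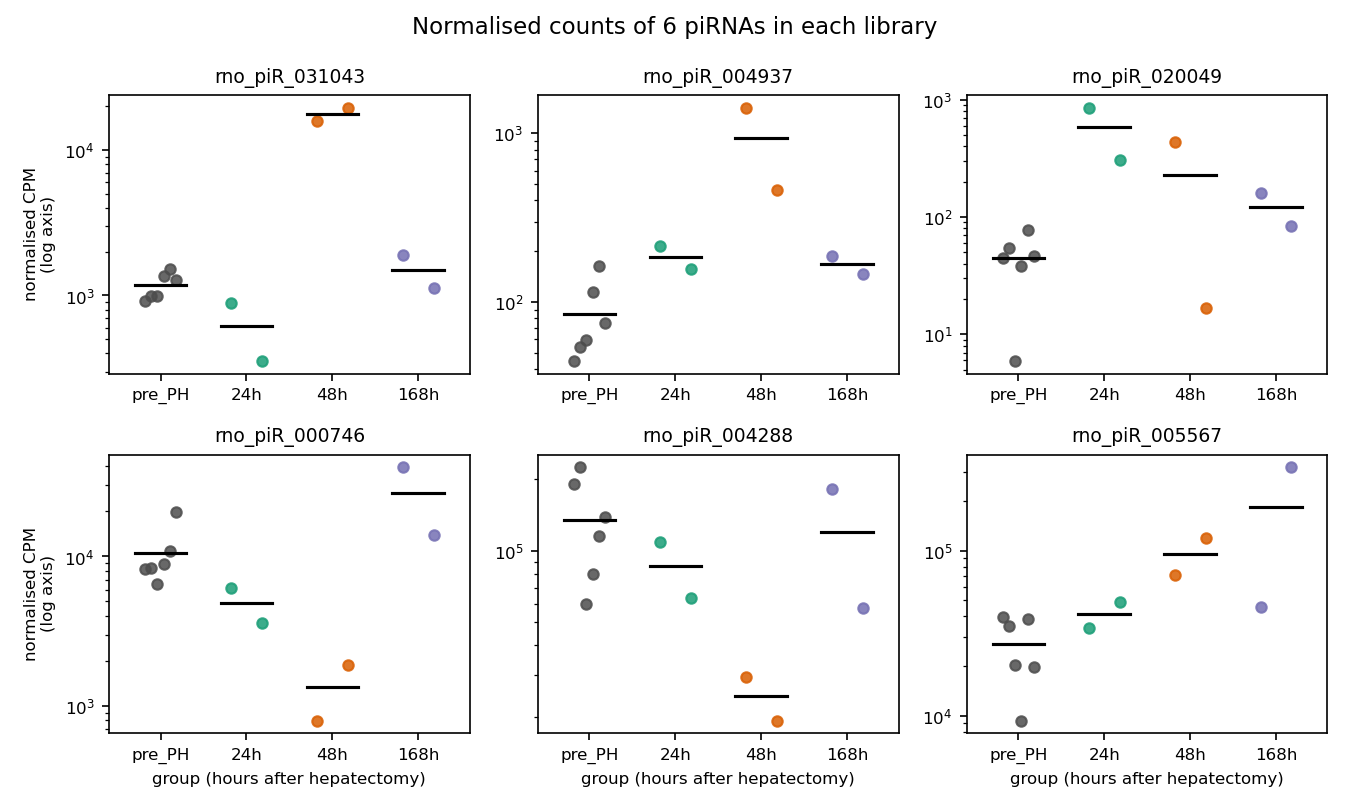
Normalised CPM (log vertical axis) of 6 piRNAs in each library, by group (horizontal axis); points are libraries and lines group means. The 48h libraries lie above the pre_PH range for rno_piR_031043 (15860 and 19570 against 917 to 1528) and below it for rno_piR_000746 and rno_piR_004288, while 168h replicate 2 alone carries the high mean of rno_piR_005567.

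The piRNAs found in every library both rose and fell at 48h. Of the 60 tested piRNAs seen in all 12 libraries, 12 rose, 10 fell and 38 did not pass, with a median log2 fold change of -0.588, and 11 rose and 10 fell adjusted over the list alone. Of the other 20 tested, 15 rose and none fell, but a piRNA missing from some libraries enters the test mainly through the group where it is high. Only 6 of these 20 passed the count filter without the 48h libraries, against 56 of the 60, so a comparison of the 60 with the rest decides nothing at 48h or between 48h and another time. Among the 20 most abundant piRNAs, 2 rose, 4 fell and 14 did not pass, with a median of -0.914 against 0.738 outside the list (camera adjusted p = 0.00532, adjusted p = 0.0983 with an estimated correlation), and 1 rose and 4 fell adjusted over the list alone. Both lists were drawn up from these samples, so neither is independent evidence of a direction. The tested piRNAs outside the 20 most abundant include the 20 missing from some libraries. The camera tests of the 20 most abundant at 48h, or between 48h and another time, therefore decide nothing either. At 24h and 168h neither list passed (camera adjusted p of at least 0.483). The piRNAs found in all libraries had 1 rise and 1 fall at 24h and 4 rises at 168h, the 20 most abundant 0 calls at 24h and 2 rises at 168h, with the same numbers adjusted over the list alone. At 24h the median of the 20 most abundant, -0.323, lay below the -0.189 of the others while the test leaned the opposite way.

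At 168h, when regrowth is largely over, 5 piRNAs were higher than in pre_PH and none lower by edgeR, with 13 at an unadjusted p under 0.05. The log2 fold change was 3.17 ± 0.86 (SE) for rno_piR_001338, 1.91 ± 0.50 for rno_piR_002302, 1.91 ± 0.53 for rno_piR_033824 and 1.81 ± 0.52 for rno_piR_019160 (edgeR adjusted p = 0.0278, 0.0278, 0.0278 and 0.0340). For rno_piR_005567 it was 2.76 ± 0.69, but its 182400 ± 194100 normalised CPM (n = 2) came mostly from replicate 2. None of the 5 calls held throughout. None was kept without 168h replicate 2, 24h replicate 1 or 2, or 48h replicate 1, where 0, 0, 2 and 1 piRNAs passed, 1 of the 5 was kept without 168h replicate 1 or pre_PH replicate 4, 2 without 48h replicate 2 and 3 without pre_PH replicate 5 or 6. The count was also 0 with the stricter filters and with the authors' library total, 2 with scaling to the piRNA total, and 4 rises and 1 fall with DESeq2 size factors.

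Comparing the times directly, rno_piR_031043 stood out between 24h and 48h, with a log2 fold change of 4.83 ± 0.74 (SE, edgeR adjusted p = 9.4e-05), from 622 ± 378 to 17710 ± 2625 normalised CPM (n = 2 each). For rno_piR_033815, unseen in both 24h libraries, the level at 48h was at least 16-fold higher. The ratio was 34.8 (95% counting interval 6.04 to 1390) for rno_piR_011266 and 29.5 (5.09 to 1180) for rno_piR_007474, each with 1 read at 24h, and rno_piR_010458 had a log2 fold change of 4.26 ± 1.21. Those of rno_piR_000324 and rno_piR_032799 were -2.60 ± 0.68 and -2.08 ± 0.67. Of these 7, only rno_piR_031043 passed in all settings and with any library left out. The other 4 rises were lost without any 1 of the 24h and 48h libraries, those of rno_piR_011266 and rno_piR_007474 also without 168h replicate 1, those of rno_piR_007474 and rno_piR_010458 also without pre_PH replicate 6, and these 3 with no filter on low counts. The fall of rno_piR_000324 was lost without 24h replicate 1 or 48h replicate 2 and with scaling to the piRNA total. That of rno_piR_032799 was lost without either 24h library or 48h replicate 2 and in 7 of 12 settings. In all 12 piRNAs rose and 2 fell, against 26 and 0 with scaling to the piRNA total, 6 and 9 with TMM without the 10 most abundant, and 32 and 1 with the authors' library total. The count fell to 1 without 24h replicate 1, 3 without 24h replicate 2 and 2 without 48h replicate 2, and went up to 26, 27 and 23 without pre_PH replicates 1, 4 and 5. Of the piRNAs found in all libraries 5 rose and 2 fell, or 3 and 1 adjusted over the list alone. Among the 20 most abundant, 1 rose and 2 fell either way (camera adjusted p = 0.00277, adjusted p = 0.0824 with an estimated correlation). The count filter bears on that camera test as at 48h, so it decides nothing.

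Between 48h and 168h, 13 piRNAs rose and 17 fell. Of the 27 piRNAs that had risen at 48h, 15 were lower at 168h than at 48h, and of the 10 that had fallen, 8 were higher at 168h. The median log2 fold change against pre_PH of the 27 was 3.14 at 48h and 0.355 at 168h, and that of the 10 was -2.43 and 0.835. Since these piRNAs were chosen for their 48h values, part of that return is what selection alone gives. The level of rno_piR_000746 reached 26740 ± 18080 normalised CPM at 168h, a log2 fold change of 4.32 ± 0.87 from 48h (SE, edgeR adjusted p = 0.0017). The changes for rno_piR_002302, rno_piR_000575, rno_piR_000127 and rno_piR_000324 were 3.56, 3.53, 3.22 and 3.02. Unseen at 168h, rno_piR_030575 was at least 13.72-fold lower than at 48h. Ratios of 48h to 168h were 36.4 (95% counting interval 9.87 to 303) for rno_piR_028365, 27.1 (7.30 to 227) for rno_piR_033815, 25.7 (4.39 to 1040) for rno_piR_035899 and 21.9 (3.71 to 885) for rno_piR_008114, which had 1 or 2 reads each at 168h. These 5 falls were all lost with a library left out: each without 168h replicate 1, all but that of rno_piR_030575 also without 48h replicate 1, those of rno_piR_035899 and rno_piR_008114 without 48h replicate 2, and that of rno_piR_035899 without 168h replicate 2. With no filter on low counts those of rno_piR_033815, rno_piR_035899 and rno_piR_008114 were lost. The rises of rno_piR_000746, rno_piR_002302 and rno_piR_000324 passed throughout, that of rno_piR_000575 was lost without 48h replicate 2 and with at least 10 counts in 4 libraries, and that of rno_piR_000127 in 4 of 12 settings. Other scalings gave 7 rises and 17 falls (piRNA total), 8 and 22 (upper quartile) and 7 and 26 (authors' library total). Fewer piRNAs were called without 48h replicate 2 or without 168h replicate 1. The piRNAs found in all libraries had 13 rises and 5 falls. For the 20 most abundant, with 6 rises and 1 fall, as many as when adjusted over the list alone in both lists, the camera adjusted p was 0.0204 and the adjusted p = 0.177 with an estimated correlation. That camera test decides nothing either, since the count filter bears on it as at 48h.

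Between 24h and 168h only rno_piR_015359 passed among 80 tested, at 16040 ± 3104 normalised CPM against 1562 ± 805, a log2 fold change of 3.36 ± 0.77 (SE, edgeR adjusted p = 0.0169). It was lost without either 24h library, 168h replicate 2, or pre_PH replicate 4 or 6. Neither list of piRNAs passed here (camera adjusted p = 0.585 and 0.828), though adjusted over the list alone 3 of the 20 most abundant rose. Over all 4 groups together, 38 of 80 piRNAs varied (edgeR joint F-test), and 21 without 48h replicate 1.

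Fold changes against pre_PH were weakly related between times across piRNAs, which are not independent replicates. Pearson's r was 0.27 for 24h with 48h, 0.06 for 48h with 168h and 0.31 for 24h with 168h. Unchanged groups set against the same pre_PH libraries gave simulated values of 0.25, 0.26 and 0.22. The covariance was 0.656 against a simulated 0.212 for 24h with 48h, 0.172 against 0.203 for 48h with 168h and 0.463 against 0.212 for 24h with 168h. With the pre_PH libraries split between the times, r was 0.27, 0.20 and 0.33. Of the rises, 1 was shared by 24h and 48h and 2 by 48h and 168h, against 0.338 and 1.69 for independent lists, and no fall was shared. The rise shared by 24h and 48h was that of rno_piR_020049. At 48h it had 440 normalised CPM in replicate 1 but 16.7 in replicate 2, within the pre_PH range of 5.94 to 76.9. With split pre_PH libraries 1 and 0 rises were shared.

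Pooling the 6 libraries after hepatectomy against the 6 of sham-operated liver gave 6 calls among 52 piRNAs tested. The piRNAs rno_piR_031043, rno_piR_020049, rno_piR_004937, rno_piR_005567 and rno_piR_010957 rose, with log2 fold changes of 3.08, 3.02, 2.91, 2.16 and 1.95, and rno_piR_000753 fell, with -1.49 ± 0.42 (SE, edgeR adjusted p = 0.0413 for each of the 6). The 48h libraries weighed heavily on the first, whose level after hepatectomy ran from 355 to 19570 normalised CPM. No call remained without pre_PH replicate 1, 2 or 4 or 48h replicate 1, 1 remained without pre_PH replicate 3 or 48h replicate 2, and 2 without pre_PH replicate 6. Scaling to the piRNA total gave 6 rises and 0 falls, upper-quartile scaling 3 and 0, and the authors' library total 2 and 1, while limma-voom made 0 calls, with 8 at an unadjusted p under 0.05. All 5 rises and the fall were among piRNAs found in all 12 libraries, as were all 52 tested, and the 20 most abundant, with 2 rises and 0 falls, gave no call as a list (camera adjusted p = 0.935, adjusted p = 0.936 with an estimated correlation).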

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

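Of the tests in this part, those of depth, of an outside source and of other splits were chosen or written after the result was seen.

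The direct comparisons of time points gave differences between groups. Between 24h and 48h, 14 piRNAs differed by edgeR, with log2 fold changes of 8.22 for rno_piR_033815 (a fitted value against 0 reads, so no bound), 4.95 for rno_piR_011266, 4.83 for rno_piR_031043, 4.66 for rno_piR_007474, 4.26 for rno_piR_010458, -2.60 for rno_piR_000324 and -2.08 for rno_piR_032799. Between 48h and 168h, 30 differed, with 4.32 for rno_piR_000746, 3.56 for rno_piR_002302, 3.53 for rno_piR_000575, 3.22 for rno_piR_000127, 3.02 for rno_piR_000324, -7.66 for rno_piR_030575 (fitted against 0 reads), -5.30 for rno_piR_028365, -4.91 for rno_piR_033815, -4.36 for rno_piR_035899 and -4.20 for rno_piR_008114. Between 24h and 168h, 1 differed, rno_piR_015359 at 3.36.

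Within pre_PH, 6 of 46 sets of values had 1 library far from the other 5. These were the normalised CPM of rno_piR_000746 in replicate 6 (19870), rno_piR_001338 in replicate 4 (38.2), rno_piR_008114, rno_piR_009544 and rno_piR_024382 in replicate 5 (71.8, 35.9 and 46.2) and rno_piR_035899 in replicate 3 (5.94, the single read there). Replicate 5 also had the highest number of piRNAs at equal depth in pre_PH, 192. For normally spread, independent values chance would flag about 1 in 20, or 2.3 sets. All of the 6 but rno_piR_000746 had low counts, with no reads in at least 1 pre_PH library. That rate does not hold for such counts, so whether 6 sets exceed chance cannot be decided.

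The number of distinct read sequences, which entered no comparison of the results, was 2159 and 3057 in the 48h libraries, above the 1192 to 1719 of pre_PH (exact permutation p = 0.0357, the smallest possible, adjusted p = 0.143). That number was not matched for depth and grows with the number of piRNAs detected. Per piRNA detected it was lower, 6.72 at 48h against 9.36 in pre_PH, with both libraries below the pre_PH range (exact permutation p = 0.0714, adjusted p = 0.286).

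At 48h more piRNAs were detected than in pre_PH. More reads left for rare species, from depth or from a smaller share of the most abundant, does not account for this: at one number of reads and without the 10 most abundant piRNAs, the lower 48h library still had 269.7 piRNAs, above the highest pre_PH library at 171. Reads of 1 outside library in fixed proportions cannot be told apart from a change in the liver. PCR copies could widen the SD of the log2 ratio of excess reads over the 15 risen piRNAs not seen everywhere (0.599 against 0.369 from counting, and 0.776 against 0.339 over the 26 of 27 risen with excess reads in both). Among the 227 names seen at 48h only, the split of reads departed from 1 ratio (Monte Carlo chi-square p = 0.0009995). That of distinct sequences did not pass (Monte Carlo chi-square p = 0.638). Its power was only 26.0%, at an assumed squared coefficient of variation of 0.35 between the libraries. More fragmented RNA is a further candidate explanation, since in 60 piRNAs found in all libraries both 48h libraries had slightly more distinct sequences at a given number of reads (median log2 residuals 0.0894 and 0.0804, mean 0.0849, against at most 0.0609 in pre_PH), though over all piRNAs detected, many of them at low counts, the number per piRNA was lower. A biological change at 48h and joint preparation of the 48h libraries stay open, as the labels give no batch.

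For the pooled comparison of 6 against 6 libraries, 100 of the 462 possible splits were drawn, the real one included. Only the real split gave 6 calls (1 of 100, the smallest share that 100 splits can give), and the highest of the others gave 4. The splits treat the 12 libraries as exchangeable, which the libraries of a time may not be, so they cannot exclude chance as the origin of the count. The calls themselves were also lost without single libraries.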

How the results depend on the processing

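Scaling to the authors' library total and thinning to one library total were chosen after the data had been seen. The other alternatives were planned. The cause of a change was not tested unless given. The counts over the named piRNAs leave out 26 uncalled values of the 10 most abundant, given after them, of which 20 changed sign in some fit. Over the named piRNAs, 659 fits under other settings left 525 on the same side of the threshold with the same direction, 128 lost the call and 6 gained it; of 660 fits with 1 library left out, 510 were the same, 145 lost it and 5 gained it, and none reversed. For the 10 most abundant piRNAs, 26 uncalled values with no fold change printed changed sign in 75 of 612 fits and passed in 2. Other scalings moved the median log2 fold change at 48h from 0.0936 to at most 0.832. Where an arm was left with 1 library, that library was assumed to vary like the other groups. Detection at 48h kept its direction in all 4 alternatives, with ratios from 1.82 to 2.36.

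With scaling to the piRNA total the calls were 1 at 24h, 2 at 168h and 26 for 24h to 48h. Upper-quartile scaling gave 1 at 24h, 22 for 24h to 48h and 3 pooled. DESeq2 size factors gave 27 for 24h to 48h, and TMM without the 10 most abundant gave 1 at 24h. The authors' library total gave 5 at 24h, 0 at 168h, 33 for 24h to 48h, 3 for 24h to 168h and 3 pooled. With no filter, and so 701 tested, there were 1 at 24h, 3 at 168h, 3 for 24h to 48h, 17 for 48h to 168h, 2 for 24h to 168h and 3 pooled. At least 10 counts in 4 libraries left 19 at 48h, 0 at 168h, 13 for 48h to 168h and 19 jointly. Only piRNAs in all 12 libraries gave 17 at 48h, 0 at 168h, 19 for 48h to 168h and 21 jointly. These filters also tested fewer piRNAs. DESeq2's test gave 4 at 24h, 31 for 24h to 48h and 4 for 24h to 168h. With limma-voom there were 1 at 24h, 1 at 168h, 23 for 24h to 48h and 0 pooled. An adjusted p under 0.1 gave 31 for 24h to 48h and 3 for 24h to 168h. Fitting only the compared groups gave 8 at 168h, 27 for 24h to 48h and 5 for 24h to 168h.

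Whether the replicate numbers pair the libraries is not known. Deviations of same-numbered libraries from their group means correlated from -0.267 to 0.298. These values cannot decide it, since the 2 libraries of a time deviate from their mean as mirror images. Replicate numbers above 2 occur only in pre_PH, so the block fitted those libraries exactly. Comparisons with pre_PH then rested on its replicates 1 and 2, and calls lost with the block do not bear on pairing. With the replicate block the calls were 1 at 24h, 27 at 48h, 0 at 168h, 12 for 24h to 48h, 26 for 48h to 168h, 0 for 24h to 168h, 37 jointly and 0 pooled.

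Leaving out each library in turn gave 0 to 5 calls at 24h, 19 to 52 at 48h, 0 to 6 at 168h, 1 to 27 for 24h to 48h, 16 to 35 for 48h to 168h, 0 to 6 for 24h to 168h, 21 to 50 jointly and 0 to 8 pooled. The ratio to pre_PH of the geometric mean piRNA share of library reads ran from 0.625 to 1.20 at 24h and from 0.868 to 1.19 at 48h, on both sides of 1. The share of the 3 most abundant piRNAs at 24h was 0.982 of pre_PH, the opposite direction to that of the 10, and at 48h 0.609. With split controls r for 48h with 168h was 0.20. Of 6 group tests that passed, 3 did with an estimated correlation, all 3 on the piRNAs found in all libraries, where the count filter largely fixes the outcome.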

Other observations

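The tests in this part were all chosen after the values had been seen.

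Among the 20 most abundant piRNAs, 6 moved together from library to library in all groups: rno_piR_005556, rno_piR_005787, rno_piR_000030, rno_piR_008639, rno_piR_000119 and rno_piR_008174. Over the 12 libraries, log2 RPM of library reads of their 15 pairs had Pearson's r from 0.729 to 0.969 and Spearman's rho from 0.615 to 0.972. The permutation p ranged from 1e-05, the smallest that 100000 permutations can give, to 0.00592, and all 15 had an adjusted p under 0.05 among 190 pairs tested, the largest 0.0487. The 6 were chosen from these same values, so that all 15 passed is no independent evidence. The piRNA share of library reads, from 0.408 to 1.25%, enters every RPM value and was not removed. Reads shared between similar records were not examined. Without the 2 libraries farthest from the median r ranged from 0.278 to 0.976, so the weakest pairs rested on those libraries. Deviations from the group means gave r from 0.842 to 0.984. Within the 6 pre_PH libraries alone r was 0.827 to 0.987 (exact permutation p of at most 0.0514). The range among sham-operated livers was wide: rno_piR_005787 ran from 5.47 to 1395 RPM of library reads, a 255-fold span, rno_piR_000030 from 7.24 to 635 and rno_piR_005556 from 40.6 to 2457. The lowest value of all 3 came from pre_PH replicate 1, and without it the spans were 17.7-fold, 18.9-fold and 9.19-fold. By contrast, rno_piR_000685 spanned 3.06-fold and rno_piR_005359 2.10-fold in the same libraries. Of the 190 pairs 24 passed in all, 20 of them positive and 4 negative. The strongest outside the 6 were rno_piR_032799 with rno_piR_000324 (r = 0.947, permutation p = 3.0e-05, adjusted p = 0.00095, r = 0.867 without the 2 farthest libraries) and rno_piR_005901 with rno_piR_005900 (r = 0.899, permutation p = 8.0e-05, adjusted p = 0.0017, r = 0.882 without them). The strongest negative one was rno_piR_005556 with rno_piR_019160 (r = -0.823, permutation p = 0.0011, adjusted p = 0.0139).

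The number of distinct read sequences of some of the most abundant piRNAs reached a ceiling. For rno_piR_000685 it was 91 in 9 of 12 libraries, for rno_piR_005556 66 in 7, and for rno_piR_005787, rno_piR_000030 and rno_piR_005359 it was 120, 78 and 36 in 2 libraries each. These 5 maxima have the form k(k+1)/2, the number of stretches above a minimum length in a sequence, as does the single sequence of rno_piR_005901, the fifth in abundance, found in all 12 libraries. Among the 50 most abundant piRNAs, 11 had a maximum shared by at least 2 libraries, and the other 5 of these, with maxima of 2 to 7, did not have that form, so that 54.55% did against 12.5% of whole numbers up to 120. One of these 5, rno_piR_001199, had 2 distinct sequences in all 12 libraries, a ceiling without that form. A candidate explanation, which these values leave undecided and which was formed from them, is that the reads counted were any stretch inside the piRNA record, of any start and end, so that fragments of longer RNAs containing that sequence may be counted with mature piRNAs. The sequences themselves were not used here, and no biological explanation was tested.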
